A study of Arabidopsis thaliana with 4 samples.

How the data were processed

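Micrococcal nuclease sequencing (MNase-seq) was done on 1 wild-type and 1 sixth-generation fas2 sample, and genomic DNA was sequenced from 1 sample of 10-day seedlings per genotype. Per the labels' protocols, leaf number 6 was taken after 38 days, fixed with 1% formaldehyde and digested with MNase at 0.2 U per µl for 8 min, and fragments of 150 ± 50 bp were cut from a gel. The labels' tissue field reads stem, and this conflict could not be settled from the data. FastQC, BWA (for the seedling libraries) and the build TAIR10 stand in the submitters' processing notes without versions.

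The main table holds nucleosome positions with their summits in each library. Its name carries that of the caller DANPOS, whose version and settings are not recorded. Per the file headers, the occupancy at the summit and at the point of the largest difference is a signal (coverage) that the authors scaled between the libraries by a method not stated. The authors' deposited table also gives the computed −log10 p of each difference and a fuzziness score per library, per the file headers. It further holds a false discovery rate for summit, point and fuzziness. How the authors computed the fuzziness score and this rate before deposit is not recorded. Positions at a rate under 0.05 had a −log10 p of at least 15.2. Adjusting these p-values for the number of positions would set a far milder bound. The rate is therefore not read here as an adjusted p-value. The headers' control and treat columns were taken as wild type and fas2, following the order of the comparison in the table's name. No labels name the samples within the columns. A second deposited file lists regions of low coverage in the fas2 genomic DNA, without coverage values or a threshold.

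The authors' p-values could be recomputed from the occupancies. For 100% of positions the value lay within 0.001 of the −log10 of a Poisson upper tail of the larger scaled value with the smaller as its mean, leaving aside 294 positions where that tail is too small to compute. The scaled values were thus treated as if they were counts. Multiples of the commonest values gave what 1 read was worth in each library, and read numbers were the nearest whole multiple.

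Log2 fold changes were computed as fas2 over wild type after adding 5 to both occupancies. Their median over all positions was 0.20, and values of genes and classes are to be read relative to that. With 1 library per genotype no test across samples was possible, and no replicate error can be given. Positions were assigned to genes by the midpoint of the summits with the RefSeq annotation of assembly TAIR10.1, which was used for names, gene classes and neighbours only. None of its coordinates are printed. The match to the authors' build was checked on the data. The lowest fas2 occupancy fell within 100 bp outside the gene edges on either side of the midpoint of each of the 5 chromosomes. All 107 listed genes were found in it. The annotation gives no strand, exons or sequence, so the planned profiles around start sites, the +1 nucleosome and the classes of exon, intron and untranslated region were replaced by profiles of unoriented gene edges and by gene, flank and intergenic classes. Upstream flanks were replaced by flanks on each side.

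Pericentromeres and 8 gene lists were defined before the data were examined. Differences were set against 1000 circular rotations along each chromosome, and list medians against 10000 random lists. Intervals for medians came from 200 resamples of 500 kb stretches. Genes were named by a rule fixed before the data were examined. It took the 10 lowest and 10 highest genes by mean fold change over at least 5 positions, FAS2, the 2 lowest and 2 highest members of each list, and the 3 lowest and 3 highest positions past the authors' threshold whose larger value was at or above the median. One item that the rule names is not reported here. Members of lists above 0.25 and below -0.25 were counted. Blocks were not planned. They were found by circular binary segmentation of 10 kb windows with a threshold of 7, at least 5 windows and an absolute ratio of at least 0.4.

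On simulated data, 6 of 6 blocks raised 1.5-fold and 6 of 6 raised 2-fold were found among 11875 windows, with 0 others. The exact binomial test called 34 of 200 positions changed 4-fold among 655605, with 0 unchanged ones, so it missed most of these changes. With so few changed positions the adjustment is stricter than in the real data, so this share does not carry over to them. A pericentromere difference of 0.3 was recovered as 0.30, and a list of 15 genes shifted by 0.5 reached percentile 100 among 37194 genes.

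No-change values came from simulated libraries with the real depths and equal occupancy. Alternatives covered thresholds, minimum occupancies, point values, pseudocounts of 1 and 10, the gene span and the matching of lists. Point values were used at 371418 positions (56.7%), where the difference lay within 200 bp of the summit, because elsewhere the table repeats 1 placeholder. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.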

Results

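Nucleosome maps were compared between wild-type Arabidopsis thaliana (accession Col-0) and sixth-generation plants of the fas2-4 mutant, to ask how nucleosomes are distributed when FAS2 is missing. FAS2 is a subunit of chromatin assembly factor 1 (CAF-1), the histone chaperone that deposits histones H3 and H4 on newly replicated DNA. Chromatin was digested with micrococcal nuclease (MNase), which cuts linker DNA and leaves nucleosomal DNA, and the protected fragments were sequenced. There was 1 MNase-seq library per genotype and 1 genomic DNA library per genotype from 10-day seedlings. The values below therefore have no replicate error, and each comparison is one of 2 libraries. The protocol describes leaf number 6 after 38 days, whereas the tissue label of the same samples reads stem.

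The deposited map held 655605 nucleosome positions on chromosomes 1 to 5. The libraries differed in depth. The commonest occupancy values were multiples of 5.21 in wild type and of 1.24 in fas2, so that 1 wild-type read was worth 4.21 times as much as 1 fas2 read after the authors' scaling. The median position had an occupancy of 15.6 in wild type, about 3 reads, and 19.3 in fas2, about 15.6 reads. In wild type 17.7% of the called positions rested on 1 read. Both libraries stopped at nearly the same number of reads, 232.7 in wild type and 231.7 in fas2. Leaving out 253 positions inside the low-coverage regions named by the authors left 655352.

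At most positions of the map both libraries had a summit. Both had one at 439914 positions (67.1%), wild type alone at 104601 (15.96%) and fas2 alone at 110837 (16.9%). Paired summits lay at most 99 bp apart, while neighbouring summits lay a median of 184 bp apart in wild type and 180 bp in fas2. Many summits could thus pair by chance, and the share expected by chance was not computed. At a false discovery rate under 0.05 in the authors' deposited table, occupancy was higher in fas2 at 23378 positions (3.57%) and lower at 20407 (3.11%). These false discovery rates compare 2 libraries, not 2 genotypes. How they were computed is not recorded, and they are not read as adjusted p-values. The positions called higher had a median occupancy of 2.60 in wild type and 33.7 in fas2, and 75.2% of them held 0 or 1 wild-type read. The positions called lower had medians of 148 in wild type and 49.2 in fas2, and 25.1% of them had a wild-type value above the highest value that the fas2 library reached. An exact binomial test on the numbers of reads, adjusted over positions, called 1089 higher and 19200 lower positions. The balance of the calls depended on the threshold and the measure, with 1742 higher and 7573 lower at a rate under 0.01 and 82053 higher and 27131 lower by the point of largest difference, both in the authors' deposited table.

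The lowest fold changes (log2 of fas2 over wild type, with 5 added to both values) were -6.96 at chromosome 3 position 15167636 in MEE38, -6.46 at chromosome 1 position 12377561 between genes, and -6.41 at chromosome 1 position 12293866 near AT1G33860. Their false discovery rates in the authors' deposited table were 0, 0 and 2e-05. Their wild-type values were 1198, 1190 and 1186, near the 1212 at which that library stopped, where the median position had 15.6. They are among the 24 positions at or above 1000 outside the low-coverage regions. Multi-copy sequence may give such a level, but copy number was not measured, so these values are uncertain. The highest were 4.43 at chromosome 3 position 7669533 near HYR1, 4.40 at chromosome 4 position 12971281 in TBL18, and 4.33 at chromosome 4 position 1753741 in the pseudogene AT4G03810. Their false discovery rates in the authors' deposited table were 0.00053, 0.00177 and 0.00197. The TBL18 and AT4G03810 positions had no wild-type signal and lay inside longer stretches raised in fas2, described below. The HYR1 position had a wild-type value of 5.21, which is 1 read. The fold changes of all these positions and their order thus depend on the 5 added.

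Positions were grouped by their wild-type level, with those inside the low-coverage regions kept. The median fold change was 1.00 at a wild-type occupancy under 10, -0.05 from 20 to 50, and -1.11 from 100 to 200. Grouping on the wild-type value itself gives a trend at this depth. Simulated libraries of equal occupancy had medians of 0.77, -0.14 and -0.15 in these groups. At the 2644 positions from 500 to 1000, of which 2433 lay in pericentromeres, it was -2.03. Equal numbers of reads in both libraries would give -2.04 there. The 156 positions at or above 1000 had a median of -5.23, with medians of 1143 in wild type and 24.8 in fas2, and 132 of them lay inside the low-coverage regions.

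**Figure D1:**
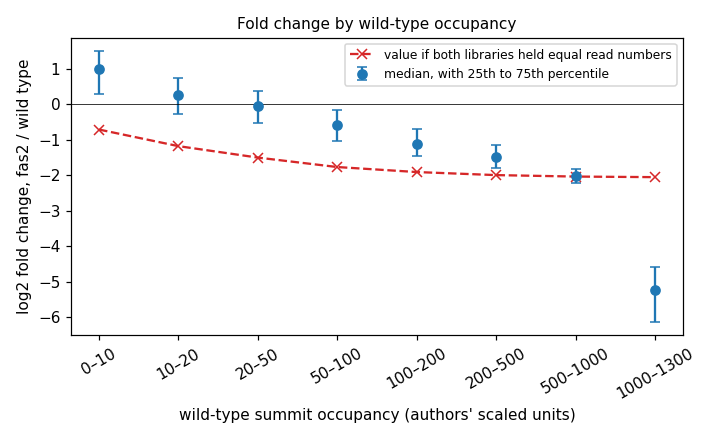
Median log2 fold change of occupancy (fas2 over wild type, vertical axis) for positions grouped by wild-type occupancy in the authors' scaled units (horizontal axis), with bars from the 25th to the 75th percentile over positions. The median falls from 1.00 to -2.03, next to the dashed line, which marks the value of equal read numbers and lies at -2.04 there, and the 156 positions of the last group, 132 of them inside the low-coverage regions, lie at -5.23.

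Distances between the summits of the libraries can be given only for paired positions, whose summits lay at most 99 bp apart, so larger shifts would not be seen. Of these positions, 95324 (21.7%, exact 95% interval 21.5 to 21.8%, counting error only) had summits over 50 bp apart, and the median distance was 29 bp. Over 30 bp the share was 46.0%. The share over 50 bp was 27.9% where wild type had 1 or 2 reads and 9.18% where it had 20 to 40. At a false discovery rate under 0.05 in the authors' deposited table, 174 positions were fuzzier in fas2 and 0 were less fuzzy. The median fuzziness score was 48.0 in wild type and 53.0 in fas2. With 7 to 12 reads in the library itself the medians were 48.5 (81866 positions) and 53.2 (127887 positions), and with 13 to 24 reads they were 48.3 and 53.0. Each library was selected by its own reads, so the sets hold different positions, and equal reads mean a lower occupancy in fas2. The median distance between neighbouring summits was 184 bp in wild type and 180 bp in fas2. The commonest distance was 110 bp in both libraries. Where the larger value reached its median, the median distances were 226.5 bp in wild type and 215 bp in fas2. These distances thus depend on which summits were called and do not measure the spacing of nucleosomes.

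Pericentromeres, which are rich in transposons and satellite repeats, did not stand apart from chromosome arms in their median fold change of the summit value. The median was 0.20 in pericentromeres and 0.21 in arms, a difference of -0.01, inside the range of -0.04 to 0.05 given by 1000 rotations of the values along each chromosome. The difference ran from -0.09 on chromosome 1 to 0.06 on chromosome 2. Lower calls in the authors' deposited table were nevertheless more frequent there, at 5.81% of pericentromeric positions against 2.23% in arms, and higher calls made up 4.17% and 3.37%. Without positions above the highest fas2 value the shares of lower calls were 3.26% and 2.06% in the authors' deposited table, and the difference of medians was 0.02.

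Pseudogenes, the class that holds the annotated transposon genes here, had the highest fold changes of the annotated classes. Their median was 0.37 over 65113 positions, with 0.38 in arms and 0.37 in pericentromeres. The rotation range for this class was 0.18 to 0.24. By the point value the class did not stand out, with a median of 1.53 for both pseudogenes and protein-coding genes. Protein-coding genes had a median of 0.25 (385732 positions), non-coding genes 0.11, flanks within 1 kb of protein-coding genes 0.07 and the remaining intergenic positions 0.05. Intergenic positions of pericentromeres had a median of -0.02, and 11.2% of them were called lower in the authors' deposited table, against 1.37% in arms. Positions above the highest fas2 value can only be called lower. Of the 2644 positions at a wild-type occupancy of 500 to 1000, 2433 lay in pericentromeres. The intergenic shares without such positions were not computed. Each of the 5 chromosomes had pseudogenes and protein-coding genes above its own median and flanks below it. Among positions whose larger value reached the median of 22.9, flanks had -0.30 and intergenic positions -0.27.

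Both genotypes had the depleted border and the dense interior of genes. Occupancy per edge of the 27432 protein-coding genes was lowest just outside the edge, at 3.11 in wild type and 2.73 in fas2. It was highest in the bin that starts 300 bp inside, at 9.58 and 9.29. The highest bin was 3.08 times the lowest in wild type and 3.40 times in fas2. The mean fold change was 0.08 within 250 bp inside the edges and 0.08 within 250 bp outside. It was lowest next to the edge, at -0.016 in the last 50 bp outside and -0.0074 in the first 50 bp inside. For genes with no other gene within 1 kb the means were -0.00098 inside and 0.08 outside.

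**Figure D2:**
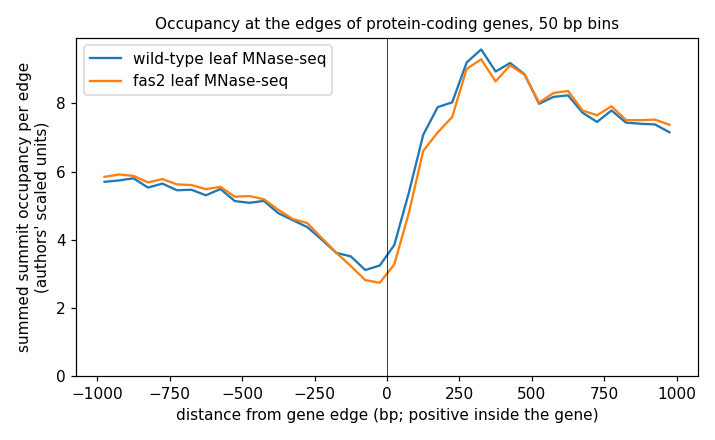
Summit occupancy summed per gene edge (vertical axis, the authors' scaled units) in 50 bp bins of distance from the edges of protein-coding genes (horizontal axis, bp, positive inside the gene), for the wild-type and fas2 leaf MNase-seq libraries. Both lines dip just outside the edge, to 3.11 in wild type and 2.73 in fas2, and peak at 9.58 and 9.29 inside.

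Over the 29072 genes with at least 5 positions, the median of the gene means was 0.28 (SD over genes 0.34). FAS2 (AT5G64630) had a mean of 0.36 over 20 positions. Its nucleosome signal does not check the genotype, since an insertion leaves the gene's sequence in place. The 10 lowest genes were MEE38 (-4.27), AT1G33860 (-2.80), AT1G38790 (-2.06), AT2G08986 (-2.050), AT2G07981 (-2.04), AT4G05612 (-2.04), AT1G40104 (-1.99), EXT11 (-1.85), AT4G01985 (-1.76) and AT1G05135 (-1.73). Their mean wild-type occupancy lay between 352 and 895, where the median position had 15.6. Multi-copy sequence may give such a level, but copy number was not measured. Reads of other copies could then not be told from their own, so the values of these genes are uncertain. At wild-type means of 553 to 673, the 5 genes from AT1G38790 to AT1G40104 lay near the -2.04 of equal read numbers in both libraries. MEE38 had -2.76 with 500 bp on each side. The 10 highest were AT4G25310 (2.103), AT4G25330 (1.73), AGL103 (1.71), AT4G25260 (1.65), AT5G33310 (1.61), AT4G04423 (1.58), AT4G05145 (1.57), AT3G56770 (1.57), AT3G09405 (1.55) and AT3G18720 (1.55). Their mean wild-type occupancy lay between 9.12 and 32.4, and 10 of the 10 were inside blocks in which neighbouring genes had raised values too.

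Such blocks were found by segmenting the ratio of summed occupancy in 11875 windows of 10 kb, leaving out positions with a wild-type occupancy of 150 or more. In 12 blocks fas2 was higher, by a median log2 ratio of 0.46 to 1.18, over 2650 kb in all. The longest ran on chromosome 4 from 1310001 to 2770000 (ratio 0.62, 1.54-fold) and held 229 protein-coding genes and 150 pseudogenes. The strongest ran on chromosome 3 from 2880001 to 2960000 (1.18, 2.26-fold). It was followed by chromosome 5 from 12560001 to 12630000 (1.09), chromosome 3 from 6390001 to 6450000 (1.01), chromosome 4 from 12920001 to 13030000 (0.97), chromosome 3 from 20950001 to 21050000 (0.92) and chromosome 1 from 4210001 to 4260000 (0.79). In 4 blocks fas2 was lower, by -0.92 to -1.29, and all 4 lay in pericentromeres. Their wild-type signal lay 0.18 to 0.90 (log2) above the flanks. The lower block on chromosome 1 held 20 positions in protein-coding genes and each of the other lower blocks 0. The cause of the lower blocks was not tested.

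**Figure D3:**
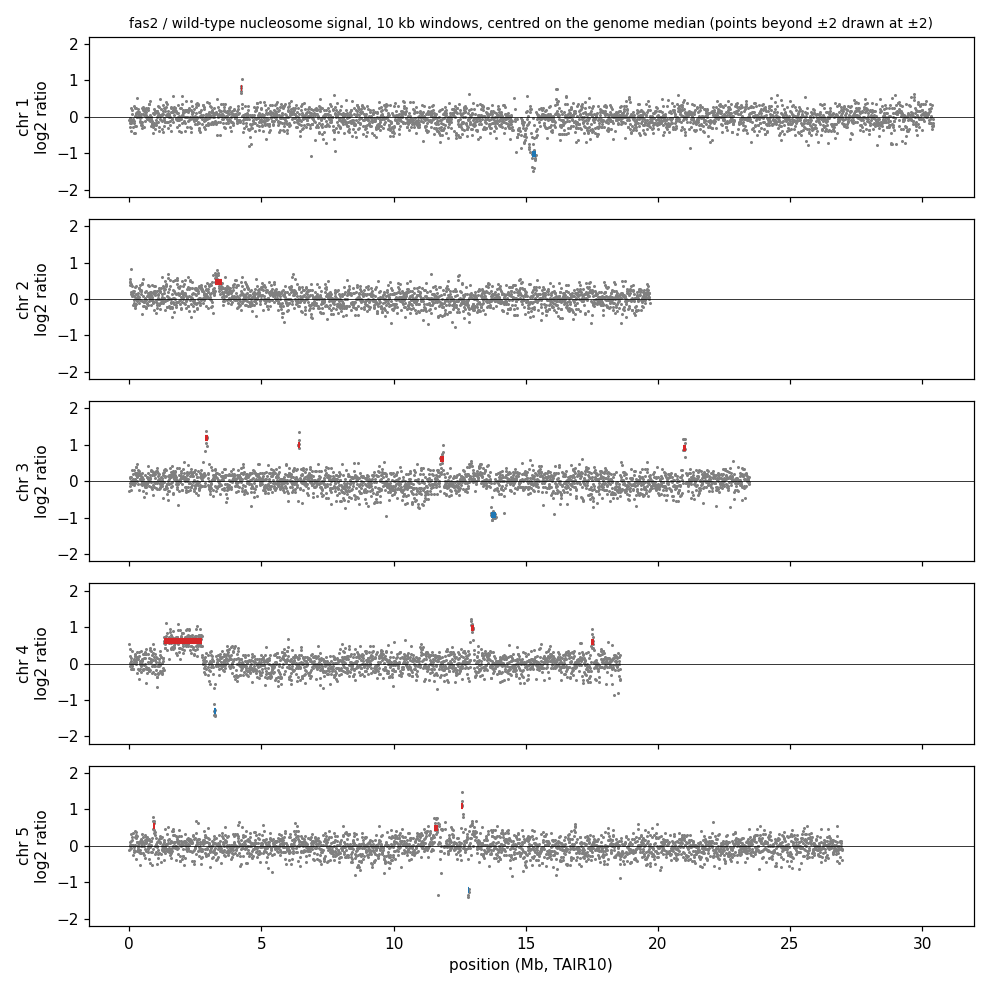
Ratio of summed nucleosome occupancy, fas2 over wild type (log2, vertical axis, centred on the genome median), in 10 kb windows along chromosomes 1 to 5 (horizontal axis, Mb). Grey points are windows, red bars the 12 blocks higher in fas2 and blue bars the 4 lower ones, drawn at their median. The block of 1460 kb on chromosome 4 lies at 0.62 and most other windows scatter about 0 with an SD of 0.23.

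Gene lists fixed beforehand were set against random lists matched on occupancy and number of positions. Of all genes with at least 5 positions, 53.7% lay above 0.25 and 6.58% below -0.25, and the counts below are to be read against those shares. Those genes include 3245 pseudogenes with a median of 0.40, against 0.26 for protein-coding genes. All listed genes are protein-coding, so the share above 0.25 may be somewhat high for them. The random lists were not matched on gene class, so pseudogenes among them may lower the percentiles below. None of the 107 listed genes lay in a block. Genes that repair DNA or signal its damage had a median fold change of 0.41, at percentile 91.7 of the random lists, with 11 of 17 members above 0.25 and 1 below -0.25. The highest member was the DNA repair gene BRCA1 (0.77), and the lowest were SMR5 (-0.33), a cell cycle inhibitor, and XRI1 (-0.14). Genes of DNA methylation and silencing had a median of 0.43 at percentile 91.2, with 9 of 10 above 0.25. By the point value the ranks of both lists fell to percentiles 56.8 and 63.5. AGO4, an Argonaute protein of RNA-directed DNA methylation, had 0.61 and the methyltransferase CMT2 0.50, while SUVH4 had 0.16 and CMT3 0.30.

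Histone chaperone genes had a median of 0.33 at percentile 57.0, with 7 of 12 above 0.25. NRP1 and ASF1A were highest, both at 0.57, and NAP1.2 (-0.21) and NRP2 (0.06) lowest. With 500 bp on each side of the gene, ASF1A had 0.12. The genes of histone H3 had a median of 0.03 at percentile 12.2, which turned to -0.19 at percentile 0.03 with 500 bp on each side, -0.012 with at least 5 positions and -0.050 by summed ratios. HTR13 had 0.59 and HTR2 0.23, whereas HTR5 had -0.67 and HTR4 -0.30. With 500 bp on each side HTR13 had 0.15. H3 genes resemble each other closely, so their values are uncertain. Of the 8 genes, 1 lay above 0.25 and 3 below -0.25.

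Epidermal patterning genes had the lowest percentile at the main settings, 2.45, with a median of 0.09 and 2 of 8 members above 0.25. By summed ratios the median was -0.065 at percentile 2.63, and with 500 bp on each side the percentile was 10.2. TRY, a repressor of trichome fate, had -0.67 and WER -0.08, against 0.53 for EGL3 and 0.41 for GL1. Photosynthesis genes had a median of 0.10 at percentile 4.72, with 5 of 15 above 0.25 and 2 below -0.25. PSAD1 (-0.54) and PSAF (-0.27) of photosystem I were lowest and the antenna genes LHCB2.1 (0.68) and LHCB4.1 (0.64) highest. Genes of salicylic acid defence had a median of 0.18 at percentile 6.41, with 8 of 20 above 0.25 and 2 below -0.25. The defence marker PR1 had 0.78 over 4 positions and PAD4 0.58, against -0.27 for WRKY70 and -0.25 for WRKY33. Genes under Polycomb control and developmental regulators had a median of 0.20 at percentile 11.7, with 7 of 17 above 0.25 and 1 below -0.25. PHE1 (0.53) and FIS2 (0.44) were highest and SEP3 (-0.42) and AP3 (-0.03) lowest. The median of this list was -0.055 at percentile 0.64 by summed ratios and 0.52 at percentile 64.7 with a pseudocount of 1, so neither its sign nor its rank held. With 500 bp on each side of the gene, TRY had -0.13, WER 0.12, PSAD1 -0.14, LHCB4.1 0.18, PR1 0.12 and SEP3 -0.14. The percentiles describe these 2 libraries and are no test of the genotypes.

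The authors' filter named 23 regions of low coverage in the fas2 genomic DNA, 46 kb in all. In 4 of them nucleosome signal was over 10 times lower in fas2. These were chromosome 2 from 1001 to 11000 (median occupancy 1108 in wild type, 35.4 in fas2), chromosome 2 from 7191001 to 7192000 (956 and 26.6), chromosome 3 from 14191001 to 14206000 (1156 and 18.01) and chromosome 5 from 3253001 to 3254000 (1060 and 16.1). The first and the third hold annotated ribosomal RNA genes, which lie in long arrays of near-identical copies. In the other 19 regions the log2 ratio of the medians ran from -0.97 to 1.06, and fas2 was higher in 14. Their median was 0.35, where the median fold change over all positions was 0.20, so a ratio above 0 is no gain in itself. Of the 156 positions with a wild-type occupancy of 1000 or more, 132 lay inside the regions and 24 outside. Nucleosome signal in these regions cannot be told from the amount of DNA, since the coverage of the genomic DNA libraries was not used here.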

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

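The exact binomial test, other pseudocounts, summed ratios, the median larger value as a minimum, leaving out blocks or positions above the highest fas2 value, and other settings for blocks were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library of each kind. Over all results and named genes, 457 of 642 alternative values stayed within the tolerance of their result and 185 did not, and 54 had another sign than the main value. The tolerance was 1.5 times for counts and the 95% interval or the SD over chromosomes for other values. The cause was not tested except where stated. The median wild-type position rests on 3 reads.

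Higher calls numbered 82053 with the point value, 1742 at a false discovery rate under 0.01 in the authors' deposited table and 1089 by the exact binomial test. Lower calls numbered 27131 with the point value and 7573 at the stricter rate. The share of shifted positions was 46.0% at 30 bp and 7.81% at 70 bp, as the thresholds dictate. It was 18.3% where the smaller value reached its median and 15.4% where it reached the median larger value. Fuzzier positions then numbered 19 and 14, and 0 at the stricter rate, since the lowest deposited rate is 0.0434.

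With the point value, taken where the libraries differ most, the pericentromere difference was -0.076. The medians were then 1.53 for protein-coding genes, 1.53 for pseudogenes, 1.45 for non-coding genes, 1.43 for flanks and 1.38 for intergenic positions, and the edge means 0.62 inside and 0.63 outside. List medians were 1.28 for chaperones, 0.70 for H3, 1.24 for DNA damage, 0.79 for salicylic acid defence, 0.80 for photosynthesis, 0.81 for Polycomb targets, 0.52 for epidermal patterning and 1.29 for DNA methylation. HTR3 (AT3G27360) turned from -0.29 to 1.88.

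Where the larger value reached the median, protein-coding genes had 0.21, non-coding genes -0.018, flanks -0.30 and intergenic positions -0.27, so the last 3 turned negative. The median distance between neighbouring summits was then 226.5 bp in wild type and 215 bp in fas2. A pseudocount of 1 gave 0.30 for protein-coding genes, 0.42 for pseudogenes, 0.14 for non-coding genes, 0.088 for flanks, 0.53 for chaperones, 0.66 for DNA damage, 0.38 for salicylic acid defence, 0.52 for Polycomb targets and 0.64 for DNA methylation. A pseudocount of 10 gave 0.20 for protein-coding genes, 0.32 for pseudogenes, 0.050 for flanks, 0.12 for Polycomb targets and 0.32 for DNA methylation. Without blocks protein-coding genes had 0.24 and flanks 0.050, and flanks of 500 bp had 0.033. Genes with no other gene within 1 kb had -0.00098 inside their edges and 0.082 outside. Summed ratios gave 0.14 for chaperones, 0.024 for salicylic acid defence, -0.055 for Polycomb targets and 0.25 for DNA methylation.

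Without positions above the highest fas2 value the pericentromere difference turned to 0.018, and lower calls in the authors' deposited table made up 3.26% of pericentromeric and 2.06% of arm positions. The H3 median was -0.19 with 500 bp on each side, -0.012 with at least 5 positions and -0.050 by summed ratios, and epidermal patterning had -0.065 by summed ratios. With the point value DNA damage genes fell to percentile 56.8 and DNA methylation genes to 63.5, since the random medians were then 1.22 and 1.24. Epidermal patterning stayed between percentiles 1.21 and 10.2 under its alternatives. The H3 list reached percentile 0.03 with 500 bp on each side and Polycomb targets ranged from 0.64 to 64.7. Blocks higher in fas2 numbered between 9 and 14.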

Other observations

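The block on chromosome 4 from 12920001 to 13030000 holds the tandem cold-response regulators CBF1 (mean log2 fold change 1.15), CBF2 (1.43) and DREB1A (0.49), the gibberellin biosynthesis gene GA20OX1 (1.496) and FKBP53 (1.04), a histone chaperone. On chromosome 3, the block from 2880001 holds the clock gene RVE8 (1.21) and the ascorbate peroxidase gene APX2 (1.36), and that from 6390001 the nucleolin gene NUC-L2 (0.81) and the DNA glycosylase gene UNG (1.09). These genes were named after their values were seen.

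Of the tests below, those of unchanged fas2 signal, of mitochondrial reads and of the 2 classes of high wild-type occupancy were chosen only after the result was seen. The raised blocks may reflect extra copies of these stretches in the fas2 plants. The difference between protein-coding and other positions, which extra copies were predicted to leave near 0, had a median of 0.059. It ran from -0.28 to 0.24 over the 12 blocks, and 3 blocks lay beyond 2 SE, so it leaves this open. The 5 added shrinks a gain more where occupancy is low, so extra copies could also give a difference other than 0. Shuffling the windows gave as many blocks in 0 of 100 shuffles. Shuffling breaks up any run of neighbouring windows, so it bears only on scatter that is independent between windows. Against their flanks the blocks had a median of 0.80 in fas2 (SD 0.36), which argues against a loss of wild-type signal alone, and -0.17 in wild type (SD 0.33), which leaves a part of it open. These medians count each block once, whatever its length, and do not hold for each block. The longest, on chromosome 4 from 1310001, had 0.32 in fas2 and -0.25 in wild type. On chromosome 3 from 11760001 fas2 lay at 0.29 and wild type at -0.31, and on chromosome 5 from 11530001 at 0.01 and -0.44. The strongest block, on chromosome 3 from 2880001, had 0.97 in fas2 and -0.09 in wild type. A chromatin difference over whole blocks was not tested, and genomic DNA coverage, which would bear on it, was not analysed here.

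The block on chromosome 2 from 3240001 to 3510000 covers the nuclear copy of the mitochondrial genome. Its wild-type signal already lay 0.85 (log2) above the flanks, consistent with organelle reads in both libraries. In fas2 it lay 1.21 above, and the cause of that excess stays open.

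At wild-type occupancies of 500 to 1000 the ratio of read numbers, fas2 over wild type, had a median of 1.00, where the depths would give 4.21. A ceiling on reads per base alike in both libraries would give such a ratio, but the medians of 119.5 reads in wild type and 121.2 in fas2 lay below the 232.7 and 231.7 at which they stopped, so the cause of the lower calls at this level, 12.9% of all lower calls, stays open. At or above 1000 the ratio was 0.093, which a common ceiling does not give. There 58.3% of the positions lay at or above the fas2 median of 19.3, and 41.7% lay below it. Their fas2 signal was thus near that of a typical position. A loss of copies that leaves about as much sequence as the reference holds would give this. A filter on the fas2 reads could give it too and was not tested, so the value cannot tell the causes apart.

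Of the positions called higher in fas2, sampling noise may make up part. Simulated libraries of equal occupancy and the real depths gave 0.254 of the real number of higher calls and 5.81% of the lower ones. This lies between the bounds set beforehand and leaves the share of noise among these calls open. The exact binomial test, which allows for counting error and nothing else, called 1089 positions higher. In simulated data it called 34 of 200 positions changed 4-fold, under a stricter adjustment than in the real data because few positions were changed. The share that it misses in the real data is not known, so a call that it leaves out is not thereby noise.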
